A study of Mus musculus with 12 samples.

How the data were processed

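Gene expression was measured by sequencing of messenger RNA (TRIzol extraction, TruSeq Stranded mRNA libraries) from 3 populations of lung CD4 T cells of BALB/c mice, sorted 40 days after infection with Nippostrongylus brasiliensis. ST2hi cells were sorted as CD25-negative, CD44-high and ST2-positive, ST2lo cells as CD25-negative, CD44-high and ST2-negative, and naive cells as CD44-low. Each population has 2 libraries. A further 6 samples of eosinophils were not analysed here.

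The deposited values are FPKM, which the authors computed with Bowtie 0.12.8, TopHat 1.3.2 and Cufflinks 2.0.2 on the mouse genome mm10, per the submitters' processing notes. The annotation and the settings of the FPKM calculation are not stated in those notes, and no scaling between the libraries was evident in the values. Each library holds 23746 lines with a gene symbol and a value. The 240 symbols that stand on several lines (702 lines) were left out. The files hold no read counts, so depth is unknown and count models were not used. Chromosome positions are those of GENCODE M21, whose assembly is the same as mm10, and this annotation is not necessarily the one the authors used.

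Genes with at least 1 FPKM in at least 2 of the 6 libraries were kept, which left 10073 genes, 156 of them short RNA genes (an annotated span under 300 nt, or a microRNA, snoRNA or snRNA symbol). Values were transformed to log2(FPKM + 1), a scale that understates differences of genes with low values. All 6 libraries entered one fit with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no covariate, and ST2hi with ST2lo, ST2hi with naive cells and ST2lo with naive cells were compared. The fit left 3 residual degrees of freedom, and limma's prior added 7.23. Tests were two-sided, and a gene passed at a Benjamini-Hochberg-adjusted p under 0.05. A fold is the ratio of the mean FPKM of both groups. Where a log2 difference is given relative to the median of all genes, its limma p-value is that of the difference before the median was subtracted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

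Gene lists, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. There were 15 lists for set tests (type 2, type 1 and cytotoxic, type 17, regulatory and follicular helper T cells, naive and central memory cells, tissue residency, immediate early genes, heat shock, cell cycle, lipid uptake and synthesis, glycolysis, repair and matrix, interferon response, checkpoint and costimulation). They were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 15 lists of a comparison. The estimate was 0.0163 for the type 17 list and 0.49 to 0.95 for the other lists, above the preset value. No list passed with it, so higher or lower as a list refers to the test at the preset correlation alone. The median of a list is that of the log2 differences of its tested members, relative to the median of all genes. Counts of members are adjusted over all genes tested or over the list alone. Another 9 lists of markers (T cells and 8 other kinds of cell) were summed per library without a test, and 1 list, of plasmacytoid dendritic cell genes, was added after the data were seen. Named genes were those past the threshold whose groups did not overlap, with a higher group mean of at least 5 FPKM, by the 10 largest and the 10 smallest log2 differences, with unnamed gene models, microRNA and snoRNA genes, ribosomal protein pseudogenes, and immunoglobulin and T cell receptor segments left out of this ranking. The 4 sort marker genes were also named, with up to 4 members of each list, first those past the threshold and, where fewer than 2 passed, those with the largest difference and a group mean of at least 1 FPKM. From these the text gives a selection. Results that need certain genes are not reported here.

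The test was tried on simulated data of this design, with 200 of 10073 genes changed in each of 10 draws. Between ST2hi and ST2lo it recovered 4.8% of 2-fold, 75.0% of 4-fold, 97.2% of 8-fold and 99.0% of 16-fold changes, and called 14.3 of the 9873 unchanged genes per draw (9.36% of its calls, where the threshold allows 5%). For ST2hi against naive cells the first 3 shares were 4.6%, 74.8% and 98.4%, and 15.6 unchanged genes were called. For ST2lo against naive cells they were 3.2%, 68.8% and 97.4%, and 12.2 unchanged genes were called. The changed genes were drawn only from those whose mean on the log scale lay above about 5 FPKM. The shares therefore describe such genes, and were not split further by expression level. Recovery of genes with lower values was not tested. It may be lower, because the scale used understates differences of genes with low values. In 200 more draws, added after the data were seen and with no gene changed, ST2hi against ST2lo gave 4.72 calls on average (at most 15), ST2hi against naive cells 4.37 (at most 17) and ST2lo against naive cells 4.47 (at most 18). Some gene was called in 184, 185 and 180 of the 200 draws in that order, where the threshold allows 5% of draws. The adjusted p-values therefore did not hold their level in these simulated data. In these draws each gene kept its overall mean and limma's moderated variance. Alternatives were a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, upper-quartile scaling, quantile normalization, only the groups compared, the replicate number as a block, no mean-variance trend, and leaving out each library in turn. Added after the data were seen were leaving out short RNA genes, summing repeated symbols, upper-quartile scaling together with the block or without short RNA genes, and, for the covariance of both comparisons with naive cells, a separate naive library for each.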

Results

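Messenger RNA was sequenced from CD4 T cells of the lungs of BALB/c mice, sorted 40 days after infection with 500 third-stage larvae of the nematode Nippostrongylus brasiliensis. Sorting divided the cells into 3 populations. ST2hi and ST2lo cells were both CD25-negative with high CD44, a surface protein kept by antigen-experienced T cells, and were split by the presence or absence of ST2, the receptor for the cytokine IL-33. Naive CD4 T cells had low CD44. Each population was represented by 2 libraries, which makes 6 libraries in all, and the values were gene expression levels in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library). The number of reads behind each value is unknown, so no counting interval or floor is given. Nothing in the labels says that the 2 libraries of a population came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Values are given as mean ± SD over the 2 libraries (n = 2), except where a library lists a gene at 0, when both libraries are given. The FPKM of a library summed to between 207821 (ST2lo replicate 1) and 360129.9 (ST2lo replicate 2). Libraries of ST2hi and ST2lo did not all group by population: in the log2 values, ST2hi replicate 2 correlated more with ST2lo replicate 2 (Pearson 0.924) than with ST2hi replicate 1 (0.904), and both ST2lo libraries correlated at 0.869. ST2lo replicate 1 stood apart on the second principal component (21.2% of the variance), at 56.8 against -27.3 to 10.7 in the other 5 libraries. Naive replicate 2 listed 2097 genes at 0, and the other 5 libraries between 7143 and 7904. A further 6 samples of lung eosinophils were not analysed here.

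Il1rl1, which encodes ST2 (chromosome 1, 40429570 to 40465415 in the mm10 assembly), separated the 3 populations. It stood at 83.4 ± 5.40 FPKM in ST2hi, 9.58 ± 4.54 FPKM in ST2lo and 0.244 ± 0.103 FPKM in naive cells. The ST2hi level was 8.71-fold that of ST2lo, with a log2 difference of 3.06 ± 0.38 (SE; limma, Benjamini-Hochberg-adjusted p = 0.0146). The ST2lo level was also above that of naive cells (log2 difference 2.68 relative to the median of all genes; limma, Benjamini-Hochberg-adjusted p = 0.00241). Cd44 stood at 48.3 ± 9.43 FPKM in ST2hi, 30.1 ± 9.04 FPKM in ST2lo and 2.30 ± 0.828 FPKM in naive cells. It was higher in both CD44-high populations than in naive cells (limma, Benjamini-Hochberg-adjusted p = 0.000302 for ST2hi and 0.00194 for ST2lo). Between ST2hi and ST2lo its difference did not pass (log2 difference 0.68 ± 0.39; limma, Benjamini-Hochberg-adjusted p = 1). Il2ra encodes CD25, whose absence defined both CD44-high populations. Its RNA was present at 14.2 ± 0.380 FPKM in ST2hi, 4.50 ± 0.193 FPKM in ST2lo and 0.532 ± 0.0379 FPKM in naive cells. Cd4 stood at 96.2 ± 28.4 FPKM, 117 ± 62.7 FPKM and 62.0 ± 11.3 FPKM in the same order, with no difference past the threshold (limma, Benjamini-Hochberg-adjusted p = 1, 0.469 and 0.446 for ST2hi with ST2lo, ST2hi with naive cells and ST2lo with naive cells). The log2 difference of Cd4 between ST2hi and naive cells was 0.61 as deposited and -0.0062 after upper-quartile scaling.

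**Figure D1:**
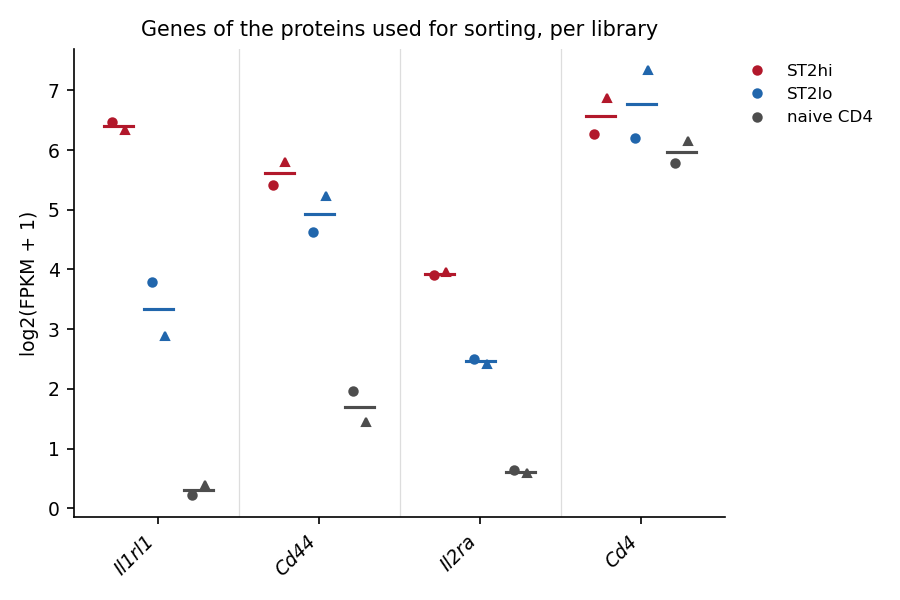
Expression of the sort marker genes Il1rl1, Cd44, Il2ra and Cd4, as log2(FPKM + 1), in each library, with circles for replicate 1, triangles for replicate 2 and bars for the mean of both. Il1rl1 lies at 87.3 and 79.6 FPKM in the ST2hi libraries and 12.8 and 6.37 FPKM in the ST2lo libraries.

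The comparison of ST2hi with ST2lo asks what distinguishes the antigen-experienced lung CD4 T cells that carry the IL-33 receptor from those that do not. Besides Il1rl1, ST2hi cells had more RNA of Pparg (chromosome 6, 115360951 to 115490399), a nuclear receptor gene of lipid metabolism. It stood at 14.4 ± 1.78 FPKM against 1.43 ± 0.231 FPKM, a 10.1-fold difference (log2 2.66 ± 0.30; limma, Benjamini-Hochberg-adjusted p = 0.00715). Lower in ST2hi was Dapl1 (chromosome 2, 59484653 to 59505020), at 1.55 ± 0.574 FPKM against 15.1 ± 0.451 FPKM (log2 -2.68 ± 0.36; limma, Benjamini-Hochberg-adjusted p = 0.0220). Another 3 genes were near 0 in ST2hi and higher in ST2lo. Siglech (chromosome 7, 55768178 to 55778925), a lectin gene of plasmacytoid dendritic cells, stood at 0 and 0.384 FPKM in the ST2hi libraries and 8.37 ± 0.0246 FPKM in ST2lo. Klk1 (chromosome 7, 44225360 to 44229618), a kallikrein protease gene, stood at 0.123 ± 0.0479 FPKM against 7.85 ± 1.62 FPKM. Irf8 (chromosome 8, 120736358 to 120756694), a transcription factor gene of dendritic and B cells, stood at 0.526 ± 0.230 FPKM against 7.22 ± 1.91 FPKM. Their log2 differences were -2.99 ± 0.31, -2.97 ± 0.31 and -2.42 ± 0.32 (limma, Benjamini-Hochberg-adjusted p = 0.00360, 0.00360 and 0.0220). The other 3 calls were the short RNA genes Mir5130, Snord71 and Snord4a (chosen after their values were seen, to complete the count), each listed at 0 in both ST2lo libraries. Mir5130 was listed at 416 and 160.4 FPKM in ST2hi and at 0 in both naive libraries. Snord71 was at 2539 and 745 FPKM in ST2hi and 1569.7 and 1319 FPKM in naive cells. Snord4a was at 2068 and 405 FPKM in ST2hi and 874 and 717 FPKM in naive cells.

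In total, 9 of 10073 genes passed limma's test after Benjamini-Hochberg adjustment, 5 higher and 4 lower in ST2hi, and 445 had an unadjusted p under 0.05. Simulated data of this design with no gene changed gave 4.72 calls on average and at least 9 in 20 of 200 draws, so the count by itself does not show that the populations differ. After upper-quartile scaling 4 were higher and 7 lower, with 7 of the 9 calls shared and those of Il1rl1 and Klk1 lost; the count was 28 with only the 4 libraries compared and, in an alternative chosen after seeing the data, 46 without short RNA genes. It was 4 with a pseudocount of 0.1, which ended the calls of Il1rl1, Pparg, Siglech, Klk1 and Irf8, and 2 without a filter on low values, where Mir5130 and Snord71 alone of the 9 still passed. A filter at 5 FPKM gave 7 and ended the calls of Pparg, Siglech, Klk1 and Irf8, and quantile normalization ended those of Il1rl1 and Klk1. Leaving out one library gave 27 genes without ST2hi replicate 1, which ended the call of Dapl1 (limma, Benjamini-Hochberg-adjusted p = 0.0900, in a range of 0.000724 to 0.283 over 18 settings), 46 without ST2hi replicate 2, 11 without ST2lo replicate 1, 62 without ST2lo replicate 2, 35 without naive replicate 1 and 27 without naive replicate 2.

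Genes of type 2 helper T cells were higher in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 1.99e-12, and 0.367 as adjusted p with an estimated correlation). Over all genes, 1 of 16 members were higher and 0 lower, against 9 and 0 adjusted over the list alone (median 0.96). Klrg1 and Nmur1, known from group 2 innate lymphoid cells and given below, differed in the same direction. Such cells also express genes of this list, and they and the T cells are not told apart here. The member past the threshold over all genes was Pparg. Cysltr1, a receptor gene for cysteinyl leukotrienes, stood at 5.56 ± 1.29 FPKM against 0.841 ± 0.834 FPKM. Epas1, a hypoxia-inducible factor gene, stood at 52.6 ± 2.14 FPKM against 14.8 ± 2.56 FPKM. Csf2, which encodes the cytokine GM-CSF, stood at 3.51 ± 0.994 FPKM against 0 and 0.704 FPKM. Their limma p-values, adjusted over the list alone with Benjamini-Hochberg, were 0.00244, 0.0179 and 0.00244. Gata3, Il5 and Il13, chosen after their values were seen, also passed adjusted over the list alone. Gata3, the master transcription factor gene of type 2 cells, stood at 117 ± 22.5 FPKM in ST2hi, 49.3 ± 6.56 FPKM in ST2lo and 9.99 ± 0.0558 FPKM in naive cells. Il5, a cytokine gene, stood at 1.69 ± 0.0357 FPKM against 0.291 ± 0.101 FPKM. Il13, another cytokine gene, stood at 3.19 ± 2.28 FPKM against 0.590 ± 0.608 FPKM. Over all genes, none of these 3 passed (limma, Benjamini-Hochberg-adjusted p = 0.602, 0.398 and 0.621). Not every member separated the populations. Il4, a cytokine gene, overlapped, at 10.4 and 21.2 FPKM in the ST2hi libraries and 13.6 and 9.73 FPKM in the ST2lo libraries. Penk was lower in ST2hi, at 0.613 and 1.69 FPKM against 1.73 and 6.04 FPKM. Relative to all genes, 14 of the 16 members had a positive and 2 a negative difference. Areg, which encodes the growth factor amphiregulin and was also chosen after its values were seen, was below the filter. It stood at 0.425 and 2.54 FPKM in the ST2hi libraries and 0.806 and 0.733 FPKM in the ST2lo libraries.

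Genes of type 1 helper and cytotoxic T cells were lower in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 3.28e-14, and 0.367 as adjusted p with an estimated correlation). The list had a median of -1.62, with 0 of 17 members higher and 0 lower over all genes (0 and 2 after upper-quartile scaling) and 1 and 9 adjusted over the list alone. The chemokine gene Ccl5 stood at 4.10 ± 3.05 FPKM against 38.7 ± 15.2 FPKM, 9.46-fold higher in ST2lo (limma, Benjamini-Hochberg-adjusted p = 0.0509). The interleukin-18 receptor gene Il18r1 stood at 8.002 ± 3.33 FPKM against 38.6 ± 14.9 FPKM (limma, Benjamini-Hochberg-adjusted p = 0.123). Both passed over all genes after upper-quartile scaling. Ly6c2 stood at 0.895 ± 1.02 FPKM against 8.82 ± 1.59 FPKM. Ifng, the gene of interferon gamma, stood at 1.31 ± 1.55 FPKM against 10.4 ± 8.14 FPKM.

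Genes of type 17 helper T cells were lower in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 4.75e-07, and 0.208 as adjusted p with an estimated correlation). A median of -1.18 was found for the list, and 0 of its 7 members were higher and 0 lower over all genes, 0 and 5 adjusted over the list alone. Ccr6, a chemokine receptor gene, stood at 1.29 ± 0.352 FPKM against 4.98 ± 1.86 FPKM. Aqp3, a water channel gene, stood at 1.19 ± 0.0584 FPKM against 3.69 ± 0.317 FPKM. Genes of follicular helper T cells were lower in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 1.02e-06, and 0.376 as adjusted p with an estimated correlation). Of 11 tested members, 0 were higher and 0 lower over all genes, and 0 and 3 adjusted over the list alone (median -0.95). Tox2, a transcription factor gene, stood at 0.646 ± 0.103 FPKM against 3.38 ± 0.00630 FPKM. Slamf6 stood at 12.7 ± 4.87 FPKM against 35.7 ± 14.8 FPKM.

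Genes of naive and central memory T cells were lower in ST2hi than in ST2lo as a list (camera, Benjamini-Hochberg-adjusted p = 4.34e-15, and 0.376 as adjusted p with an estimated correlation). Over all genes, 0 of 20 members were higher and 1 lower (0 and 2 after upper-quartile scaling), against 0 and 6 adjusted over the list alone (median -0.72). The member past the threshold over all genes was Dapl1. Actn1, which encodes an actin cross-linker, stood at 2.25 ± 1.24 FPKM against 18.5 ± 6.01 FPKM (limma, Benjamini-Hochberg-adjusted p = 0.0509), and passed after upper-quartile scaling. Genes of tissue residency were higher in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 0.00193, and 0.654 as adjusted p with an estimated correlation). With a median of 0.35, the list had 0 of 17 members higher and 0 lower over all genes and 1 and 0 adjusted over the list alone. Cxcr6, a chemokine receptor gene, stood at 47.6 ± 5.31 FPKM against 18.2 ± 4.02 FPKM. Bhlhe40, a transcription factor gene, stood at 35.4 ± 7.76 FPKM against 17.2 ± 7.69 FPKM. Immediate early genes were higher in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 2.01e-05, and 0.654 as adjusted p with an estimated correlation). A median of 0.37 was found for the list, and 0 of its 22 members were higher and 0 lower over all genes, 1 and 0 adjusted over the list alone. Fosl2 stood at 5.37 ± 1.70 FPKM against 1.28 ± 0.640 FPKM. Egr3 stood at 10.4 ± 2.59 FPKM against 3.83 ± 0.546 FPKM.

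Cell cycle genes were lower in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 3.72e-05, and 0.654 as adjusted p with an estimated correlation, which was 0.88). Of 21 tested members, 0 were higher and 0 lower over all genes, and 0 and 0 adjusted over the list alone (median -0.38). Rrm2 stood at 2.42 ± 1.91 FPKM against 5.31 ± 3.25 FPKM. Birc5 stood at 3.28 ± 2.69 FPKM against 6.04 ± 0.862 FPKM. Interferon response genes were lower in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 4.63e-06, and 0.483 as adjusted p with an estimated correlation). Over all genes, 0 of 18 members were higher and 0 lower, against 0 and 0 adjusted over the list alone (median -0.51). Ifit1 stood at 0.433 ± 0.121 FPKM against 1.85 ± 0.653 FPKM. Irf7 stood at 11.7 ± 3.28 FPKM against 18.3 ± 1.001 FPKM. Siglech and Irf8 of plasmacytoid dendritic cells, which also express Irf7, differed in the same direction, and such cells and the T cells are not told apart here. The naive libraries held 0.127 and 0.0972 FPKM of Siglech and 17.4 and 14.03 FPKM of Irf7. The other 6 lists did not pass with camera. Regulatory T cell genes had a median of -0.19, opposite in sign to the direction of the test (camera, Benjamini-Hochberg-adjusted p = 0.967). The median of heat shock genes was 0.14, and -0.0194 after quantile normalization (camera, Benjamini-Hochberg-adjusted p = 0.614). The medians were 0.10 for lipid uptake and synthesis, 0.23 for glycolysis, 0.20 for repair and matrix genes and -0.19 for checkpoint and costimulation genes (camera, Benjamini-Hochberg-adjusted p = 0.208, 0.0983, 0.860 and 0.599). Adjusted over the list alone, 1 regulatory gene, Il2ra, was higher in ST2hi and 1, Folr4, lower. Folr4, a folate receptor family gene, stood at 10.1 ± 4.83 FPKM against 33.6 ± 8.08 FPKM. Of the repair and matrix genes, 2 were higher and 2 lower on that adjustment. Adam8, a metalloprotease gene and one of the higher, stood at 12.4 ± 3.78 FPKM against 4.32 ± 1.77 FPKM, and Igfbp7, the other, at 6.91 ± 2.24 FPKM against 0 and 2.55 FPKM. Ctsh and Ctsl, cathepsin protease genes, were the lower ones, Ctsh at 0 and 0.339 FPKM against 4.32 ± 2.04 FPKM and Ctsl at 0.2002 ± 0.199 FPKM against 3.01 ± 0.630 FPKM. Over all genes these 4 did not pass (limma, Benjamini-Hochberg-adjusted p = 0.375, 0.645, 0.0624 and 0.0884). No call was made for the following genes. Plin2, whose protein coats lipid droplets, stood at 5.204 ± 0.280 FPKM against 1.505 ± 1.18 FPKM. Slc2a3, a glucose transporter gene, stood at 8.87 ± 1.15 FPKM against 6.27 ± 1.31 FPKM. Tnfsf14 stood at 8.73 ± 1.57 FPKM against 4.96 ± 1.11 FPKM. Pdcd1, which encodes PD-1, stood at 2.45 ± 0.871 FPKM against 4.65 and 5.75 FPKM.

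Some markers of other cells differed between these populations when adjusted over the list alone. Among genes known from group 2 innate lymphoid cells, Klrg1 stood at 5.10 ± 1.15 FPKM in ST2hi against 0.579 ± 0.427 FPKM in ST2lo. Nmur1, a neuropeptide receptor gene, stood at 2.08 ± 0.583 FPKM against 0.158 and 0 FPKM in the ST2lo libraries. Their limma, Benjamini-Hochberg-adjusted p-values were 0.0626 and 0.143 over all genes, and 0.000383 and 0.00101 adjusted over the list alone. Cd74, which encodes the invariant chain of class II antigen presentation, stood at 2.14 ± 0.526 FPKM in ST2hi, 13.98 ± 2.95 FPKM in ST2lo and 1.18 ± 0.506 FPKM in naive cells. Between ST2hi and ST2lo it missed the threshold (limma, Benjamini-Hochberg-adjusted p = 0.0509).

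**Figure D2:**
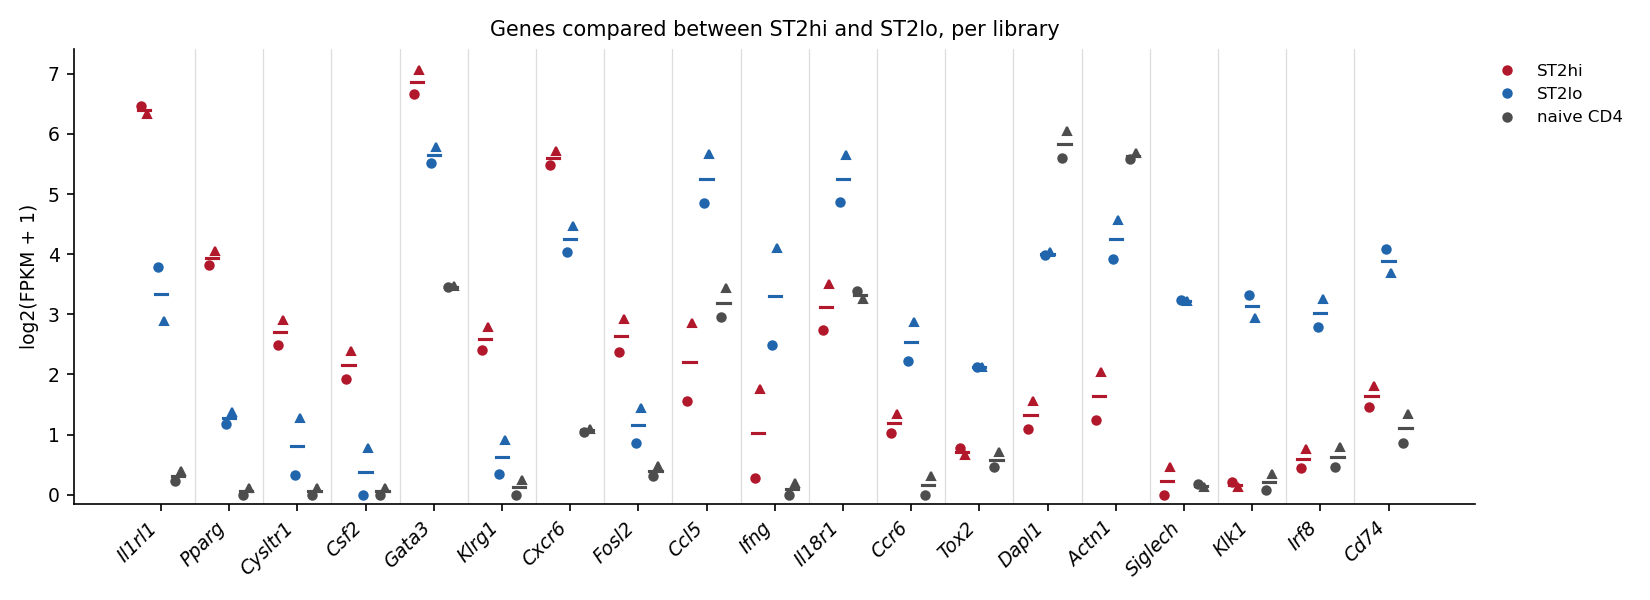
Expression, as log2(FPKM + 1), of genes named in the comparison of ST2hi with ST2lo, in each library of the 3 populations, with circles for replicate 1, triangles for replicate 2 and bars for the mean of both. Pparg lies at 13.1 and 15.6 FPKM in the ST2hi libraries and 1.26 and 1.59 FPKM in the ST2lo libraries.

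The comparison of ST2hi with naive cells asks how the ST2-bearing cells of the infected lung differ from CD4 T cells with low CD44. The median log2 difference of all genes against naive cells was 0.42 for ST2hi and 0.34 for ST2lo as deposited. After upper-quartile scaling these medians were -0.06 and -0.05. Short RNA genes made up 66.6% and 61.2% of the FPKM sum in the naive libraries. Their share was 59.2% and 45.5% in the ST2hi libraries and 42.7% and 45.8% in the ST2lo libraries. Whether this share caused the shift was not tested. The log2 differences of both comparisons are therefore given relative to the medians as deposited. The limma p-values beside them test the differences before this subtraction, not the relative ones. S100a4 (chromosome 3, 90603771 to 90606045) and S100a6 (chromosome 3, 90612882 to 90624181), which encode calcium-binding proteins, had the largest differences of the ranked genes. Short RNA genes were left out of the ranking, and those called reached relative log2 differences from -9.18 to 8.63. S100a4 stood at 232 ± 42.2 FPKM in ST2hi and 0 and 0.482 FPKM in the naive libraries. S100a6 stood at 132 ± 22.1 FPKM in ST2hi and 0 and 0.828 FPKM in the naive libraries. Their relative log2 differences were 7.14 ± 0.41 and 6.19 ± 0.41 (SE; limma, Benjamini-Hochberg-adjusted p = 7.75e-06 and 1.69e-05). Dapl1 stood at 1.55 ± 0.574 FPKM against 56.3 ± 12.1 FPKM. Igfbp4 (chromosome 11, 99041244 to 99054392), which encodes a binding protein of insulin-like growth factors, stood at 4.53 ± 1.18 FPKM against 118 ± 11.4 FPKM. These were the lowest of the ranked genes in ST2hi, with relative log2 differences of -4.92 ± 0.36 and -4.86 ± 0.42 (limma, Benjamini-Hochberg-adjusted p = 9.05e-05 and 0.000245).

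Of the other ranked genes among the 10 largest differences, 7 besides Il1rl1 are given here. Ccr2, a chemokine receptor gene (chromosome 9, 124101950 to 124113557), stood at 56.4 ± 8.42 FPKM against 0.371 ± 0.258 FPKM. Cxcr6, another, stood at 47.6 ± 5.31 FPKM against 1.10 ± 0.0483 FPKM. Mns1 stood at 45.5 ± 23.7 FPKM against 0.528 ± 0.257 FPKM. Csf1, a growth factor gene, stood at 37.1 ± 15.99 FPKM against 0.634 ± 0.306 FPKM. Ahnak, which encodes a large scaffold protein, stood at 361 ± 34.8 FPKM against 15.9 ± 3.23 FPKM. Lmna, the gene of lamin A, stood at 26.5 ± 0.0332 FPKM against 0.381 ± 0.389 FPKM. Plac8 stood at 22.9 ± 15.7 FPKM in ST2hi and was listed at 0 in both naive libraries. Relative log2 differences of the first 6 lay between 3.92 for Lmna and 4.97 for Ccr2 (limma, Benjamini-Hochberg-adjusted p = 9.05e-05 and 4.08e-05). The ranked genes lowest in ST2hi included Actn1, with relative log2 difference -4.41 (limma, Benjamini-Hochberg-adjusted p = 0.000314). Actn1 stood at 2.25 ± 1.24 FPKM against 48.7 ± 2.36 FPKM. Als2cl stood at 1.38 ± 0.518 FPKM against 21.9 ± 1.63 FPKM. Rapgef4 stood at 0.258 ± 0.171 FPKM against 7.21 ± 0.625 FPKM. Atp1b1, a sodium pump subunit gene, stood at 0.978 ± 0.843 FPKM against 11.4 ± 2.55 FPKM. Amigo2 stood at 0.734 ± 0.583 FPKM against 8.80 ± 0.115 FPKM. Ccr7, a homing receptor gene, stood at 5.59 ± 1.91 FPKM against 47.7 ± 3.47 FPKM. Beta-s, a beta globin gene of red blood cells whose reads can be shared with its paralogs, stood at 19.7 ± 21.04 FPKM in ST2hi against 196 ± 93.5 FPKM in naive cells. It passed as deposited (limma, Benjamini-Hochberg-adjusted p = 0.0456) and not after upper-quartile scaling.

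By limma with Benjamini-Hochberg adjustment, 560 of 10073 genes passed, 490 higher and 70 lower in ST2hi. Short RNA genes made up 4 of the higher (Mir1938, Mir3091, Mir5130 and Mir671, chosen after their values were seen; Mir3091 and Mir671 did not pass after upper-quartile scaling) and 9 of the lower calls. After upper-quartile scaling 471 were higher and 408 lower, with 447 of the 560 calls shared. The total was 883 after quantile normalization, 100 without a filter on low values, 1520 with only the 4 libraries compared and, in an alternative chosen after seeing the data, 953 without short RNA genes. Leaving out one library gave 197 genes without naive replicate 1, 333 without naive replicate 2, 267 without ST2hi replicate 2, 1505 without ST2lo replicate 1 and 1507 without ST2lo replicate 2, and ended 9, 9, 10, 0 and 0 of the 50 named calls (and 3 without ST2hi replicate 1).

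Type 2 helper T cell genes were higher in ST2hi than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 2.47e-12, and 0.511 as adjusted p with an estimated correlation). The list had a median of 1.95, with 13 of 16 members higher and 0 lower over all genes (11 and 1 after upper-quartile scaling) and 15 and 1 adjusted over the list alone. Ccr4, a chemokine receptor gene, stood at 19.2 ± 0.751 FPKM against 0.178 ± 0.0992 FPKM. Maf, a transcription factor gene, stood at 36.8 ± 4.63 FPKM against 1.86 ± 0.502 FPKM. Il9r, which encodes the interleukin-9 receptor, stood at 12.5 ± 1.01 FPKM against 0.0852 ± 0.0158 FPKM. Pparg stood at 14.4 ± 1.78 FPKM against 0 and 0.0860 FPKM. Genes of tissue residency were higher in ST2hi than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 6.77e-06, and 0.511 as adjusted p with an estimated correlation). A median of 1.10 was found for the list, and 8 of its 17 members were higher and 0 lower over all genes, 12 and 0 adjusted over the list alone. Bhlhe40 stood at 35.4 ± 7.76 FPKM against 0.820 ± 0.0542 FPKM. Rgs1, a regulator of G protein signalling, stood at 132 ± 93.3 FPKM against 5.65 ± 0.317 FPKM. Repair and matrix genes were higher in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 8.41e-10, and 0.511 as adjusted p with an estimated correlation). Of 16 tested members, 10 were higher and 0 lower over all genes (10 and 1 after upper-quartile scaling), and 13 and 1 adjusted over the list alone (median 2.28). S100a4 and S100a6 are among them. Lgals1, a galectin gene, stood at 166 ± 60.8 FPKM against 8.15 ± 2.31 FPKM.

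Genes of regulatory T cells were higher in ST2hi than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 4.95e-05, and 0.511 as adjusted p with an estimated correlation). Over all genes, 8 of 15 members were higher and 0 lower, against 10 and 0 adjusted over the list alone (median 1.65). Nrp1 stood at 27.1 ± 1.63 FPKM against 0.977 ± 0.764 FPKM. Ctla4, an inhibitory receptor gene, stood at 9.69 ± 6.005 FPKM against 0.427 ± 0.0361 FPKM. Tnfrsf4, which encodes OX40, stood at 23.4 ± 3.07 FPKM against 2.85 ± 0.728 FPKM. Checkpoint and costimulation genes were higher in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 6.84e-05, and 0.511 as adjusted p with an estimated correlation). With a median of 1.21, the list had 8 of 16 members higher and 0 lower over all genes (7 and 1 after upper-quartile scaling) and 11 and 0 adjusted over the list alone. Icos, a costimulatory receptor gene, stood at 19.4 ± 13.0 FPKM against 0.600 ± 0.206 FPKM. Tnfsf14 stood at 8.73 ± 1.57 FPKM against 0 and 0.129 FPKM. Immediate early genes were higher in ST2hi than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 8.41e-05, and 0.539 as adjusted p with an estimated correlation). A median of 0.81 was found for the list, and 4 of its 22 members were higher and 0 lower over all genes, 15 and 0 adjusted over the list alone. Fosb stood at 30.6 ± 8.76 FPKM against 3.04 ± 0.309 FPKM. Junb stood at 201 ± 43.2 FPKM against 53.5 ± 6.29 FPKM. Glycolysis genes were higher in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 0.000884, and 0.511 as adjusted p with an estimated correlation). Of 16 tested members, 2 were higher and 0 lower over all genes (5 and 0 after upper-quartile scaling), and 10 and 0 adjusted over the list alone (median 0.69). Slc2a3 stood at 8.87 ± 1.15 FPKM against 1.90 ± 0.495 FPKM. Tpi1, a glycolytic isomerase gene, stood at 8.21 ± 2.41 FPKM against 2.15 ± 0.232 FPKM. Cell cycle genes were higher in ST2hi as a list (camera, Benjamini-Hochberg-adjusted p = 0.0468, and 0.756 as adjusted p with an estimated correlation). Over all genes, 1 of 21 members were higher and 0 lower, against 1 and 0 adjusted over the list alone (median 0.34). Mki67, a proliferation marker, stood at 11.5 ± 8.96 FPKM against 0.975 ± 0.0670 FPKM.

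Genes of naive and central memory T cells were lower in ST2hi than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 5.86e-27, and 0.511 as adjusted p with an estimated correlation). The list had a median of -1.60, with 0 of 20 members higher and 8 lower over all genes (0 and 16 after upper-quartile scaling) and 1 and 12 adjusted over the list alone. Dapl1, Igfbp4, Actn1 and Ccr7 are among them. Interferon response genes were lower in ST2hi than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 0.000125, and 0.511 as adjusted p with an estimated correlation). A median of -0.75 was found for the list, and 0 of its 18 members were higher and 0 lower over all genes (0 and 3 after upper-quartile scaling), 0 and 0 adjusted over the list alone. Ifit1 stood at 0.433 ± 0.121 FPKM against 1.83 ± 0.0892 FPKM. Igtp, a GTPase gene, stood at 16.4 ± 6.16 FPKM against 26.8 ± 2.02 FPKM. No call was made for the type 1 and cytotoxic list, whose median was 0.0349 after upper-quartile scaling (camera, Benjamini-Hochberg-adjusted p = 0.145). Of 17 tested members, 3 were higher and 1 lower over all genes (3 and 2 after upper-quartile scaling), and 3 and 1 adjusted over the list alone (median -0.05). Cxcr3, a chemokine receptor gene, stood at 3.25 ± 1.83 FPKM against 0.174 ± 0.174 FPKM. Prf1, which encodes perforin, stood at 0.481 ± 0.128 FPKM against 4.06 ± 1.92 FPKM. Type 17 genes were not called as a list (camera, Benjamini-Hochberg-adjusted p = 0.0751). Over all genes, 2 of 7 members were higher and 0 lower, against 3 and 0 adjusted over the list alone (median 0.20). Rora, a transcription factor gene, stood at 19.95 ± 2.16 FPKM against 0.586 ± 0.148 FPKM. Ahr, the aryl hydrocarbon receptor gene, stood at 6.46 ± 1.45 FPKM against 0.328 ± 0.315 FPKM. Lipid genes were not called either (camera, Benjamini-Hochberg-adjusted p = 0.172). With a median of 0.07, the list had 2 of 16 members higher and 0 lower over all genes and 3 and 0 adjusted over the list alone. Plin2 stood at 5.204 ± 0.280 FPKM against 0.568 ± 0.570 FPKM. Fabp5, a fatty acid binding protein gene, stood at 5.72 ± 1.42 FPKM against 1.51 ± 0.0649 FPKM, and did not pass after upper-quartile scaling. Cxcr3, Prf1, Rora, Ahr, Plin2 and Fabp5 passed as deposited (limma, Benjamini-Hochberg-adjusted p = 0.0390, 0.0239, 0.000231, 0.00230, 0.0169 and 0.0294). Follicular helper genes had a test direction opposite to their median, which was -0.0096 after quantile normalization (camera, Benjamini-Hochberg-adjusted p = 0.905). A median of 0.01 was found for the list, and 1 of its 11 members were higher and 0 lower over all genes (1 and 1 after upper-quartile scaling), 2 and 0 adjusted over the list alone. Pdcd1 stood at 2.45 ± 0.871 FPKM against 0 and 0.741 FPKM. Pdcd1 missed the threshold (limma, Benjamini-Hochberg-adjusted p = 0.0580). Heat shock genes were not called (camera, Benjamini-Hochberg-adjusted p = 0.631; median 0.26). Klrg1 stood at 5.10 ± 1.15 FPKM in ST2hi and 0 and 0.184 FPKM in the naive libraries (limma, Benjamini-Hochberg-adjusted p = 0.00204).

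The comparison of ST2lo with naive cells asks the same of the antigen-experienced cells without the IL-33 receptor. S100a4 and S100a6 again had the largest differences of the ranked genes, and the short RNA genes called, which were not ranked, lay from -11.50 to 9.85 in relative log2 difference. S100a4 stood at 199 ± 45.6 FPKM in ST2lo and S100a6 at 77.0 ± 13.7 FPKM. Their relative log2 differences were 6.998 ± 0.41 and 5.50 ± 0.41 (SE; limma, Benjamini-Hochberg-adjusted p = 9.21e-06 and 5.59e-05). Myo1f, an unconventional myosin gene (chromosome 17, 33555707 to 33607764), stood at 25.6 ± 6.68 FPKM against 0.244 ± 0.237 FPKM. Itgb1, an integrin gene (chromosome 8, 128685654 to 128733200), stood at 88.4 ± 57.0 FPKM against 2.97 ± 0.511 FPKM. Their relative log2 differences were 4.07 ± 0.35 and 3.99 ± 0.52 (limma, Benjamini-Hochberg-adjusted p = 0.000147 and 0.00189). Igfbp4 was the lowest ranked gene, at 6.77 ± 3.84 FPKM against 118 ± 11.4 FPKM (relative log2 difference -4.37 ± 0.42; limma, Benjamini-Hochberg-adjusted p = 0.000984). Als2cl (chromosome 9, 110879870 to 110900530) followed, at 2.81 ± 1.18 FPKM against 21.9 ± 1.63 FPKM (relative log2 difference -2.96 ± 0.35; limma, Benjamini-Hochberg-adjusted p = 0.00355).

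The rest of the 10 largest differences of ranked genes lay between 3.36 for Fam129a and 3.60 for Ahnak relative to all genes (limma, Benjamini-Hochberg-adjusted p = 0.000978 and 0.00106). Ahnak stood at 259.8 ± 50.1 FPKM against 15.9 ± 3.23 FPKM. Ccr4 stood at 17.1 ± 4.31 FPKM against 0.178 ± 0.0992 FPKM. Lgals1 stood at 128 ± 52.1 FPKM against 8.15 ± 2.31 FPKM. Il2rb, an interleukin-2 receptor gene, stood at 24.9 ± 11.7 FPKM against 0.879 ± 0.613 FPKM. Cxcr3 stood at 15.4 ± 7.98 FPKM against 0.174 ± 0.174 FPKM. Fam129a stood at 15.8 ± 7.36 FPKM against 0.226 ± 0.0570 FPKM. Genes lower in ST2lo included Rapgef4 and Sox4 (limma, Benjamini-Hochberg-adjusted p = 0.00357 and 0.0440). Rapgef4 stood at 0.495 ± 0.525 FPKM against 7.21 ± 0.625 FPKM. Amigo2 stood at 1.14 ± 0.662 FPKM against 8.80 ± 0.115 FPKM. Treml2 stood at 2.65 ± 1.38 FPKM against 14.8 ± 1.83 FPKM. Dapl1 stood at 15.1 ± 0.451 FPKM against 56.3 ± 12.1 FPKM. Bach2, a transcription factor gene, stood at 1.27 ± 0.729 FPKM against 6.70 ± 0.319 FPKM. Sox4, another, stood at 1.06 ± 0.755 FPKM against 6.04 ± 2.40 FPKM. Inadl stood at 1.03 ± 0.346 FPKM against 5.12 ± 0.950 FPKM. Bambi-ps1, a pseudogene whose reads can be shared with its parent gene, stood at 0.740 ± 0.790 FPKM against 6.33 ± 0.417 FPKM.

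By limma with Benjamini-Hochberg adjustment, 290 of 10073 genes passed, 262 higher and 28 lower in ST2lo. Among these, 1 higher (Mir1982, chosen after its values were seen and not passing after upper-quartile scaling) and 12 lower calls were of short RNA genes. After upper-quartile scaling 268 were higher and 140 lower, with 227 of the 290 calls shared. The total was 36 without a filter on low values and, in an alternative chosen after seeing the data, 498 without short RNA genes. Leaving out one library gave 114 genes without naive replicate 1, 163 without naive replicate 2, 639 without ST2lo replicate 1 and 184 without ST2lo replicate 2, and ended 11, 12, 2 and 12 of the 47 named calls.

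Genes of type 17 helper T cells were higher in ST2lo than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 1.61e-08, and 0.151 as adjusted p with an estimated correlation). Of 7 tested members, 5 were higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone (median 1.40). Rora stood at 16.5 ± 5.27 FPKM against 0.586 ± 0.148 FPKM. Ccr6 stood at 4.98 ± 1.86 FPKM against 0 and 0.241 FPKM. Genes of type 1 helper and cytotoxic T cells were higher in ST2lo than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 5.92e-05, and 0.454 as adjusted p with an estimated correlation). Over all genes, 7 of 17 members were higher and 1 lower, against 9 and 1 adjusted over the list alone (median 0.71). Tbx21, a transcription factor gene, stood at 5.55 ± 0.986 FPKM against 0.196 ± 0.194 FPKM. Ifng stood at 10.4 ± 8.14 FPKM against 0 and 0.142 FPKM. Nkg7, a cytotoxic granule gene, stood at 7.40 ± 3.76 FPKM against 0.289 ± 0.0865 FPKM. Type 2 helper T cell genes were higher in ST2lo than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 3.33e-06, and 0.426 as adjusted p with an estimated correlation). The list had a median of 0.94, with 6 of 16 members higher and 0 lower over all genes (7 and 1 after upper-quartile scaling) and 9 and 1 adjusted over the list alone. Maf stood at 28.6 ± 8.05 FPKM against 1.86 ± 0.502 FPKM. Il4, a cytokine gene, stood at 11.7 ± 2.77 FPKM against 0 and 0.897 FPKM. Follicular helper genes were higher in ST2lo than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 0.00129, and 0.454 as adjusted p with an estimated correlation). A median of 0.52 was found for the list, and 4 of its 11 members were higher and 0 lower over all genes, 6 and 0 adjusted over the list alone. Pdcd1 stood at 4.65 and 5.75 FPKM against 0 and 0.741 FPKM. Tox2 stood at 3.38 ± 0.00630 FPKM against 0.503 ± 0.177 FPKM. Tox2 passed as deposited (limma, Benjamini-Hochberg-adjusted p = 0.0237) and not after upper-quartile scaling. With a filter at 5 FPKM the list did not pass (camera, Benjamini-Hochberg-adjusted p = 0.301), and its median was -0.0931. Genes of regulatory T cells were higher in ST2lo than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 3.08e-08, and 0.426 as adjusted p with an estimated correlation). Of 15 tested members, 8 were higher and 0 lower over all genes, and 10 and 0 adjusted over the list alone (median 1.55). Ctla4 stood at 12.4 ± 10.9 FPKM against 0.427 ± 0.0361 FPKM. Ikzf2, which encodes Helios, stood at 6.57 ± 4.44 FPKM against 0.244 ± 0.0473 FPKM. Among markers of antigen-presenting cells, Cd74 stood at 13.98 ± 2.95 FPKM against 1.18 ± 0.506 FPKM (limma, Benjamini-Hochberg-adjusted p = 0.00194).

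Checkpoint and costimulation genes were higher in ST2lo as a list (camera, Benjamini-Hochberg-adjusted p = 4.05e-08, and 0.426 as adjusted p with an estimated correlation). Over all genes, 7 of 16 members were higher and 0 lower, against 10 and 0 adjusted over the list alone (median 1.16). Icos stood at 13.2 ± 6.91 FPKM against 0.600 ± 0.206 FPKM. Tnfsf11, which encodes RANKL, stood at 8.36 ± 0.242 FPKM against 0 and 0.525 FPKM. Residency genes were higher in ST2lo as a list (camera, Benjamini-Hochberg-adjusted p = 2.36e-05, and 0.454 as adjusted p with an estimated correlation). With a median of 0.55, the list had 5 of 17 members higher and 0 lower over all genes (6 and 1 after upper-quartile scaling) and 7 and 0 adjusted over the list alone. Cxcr6 stood at 18.2 ± 4.02 FPKM against 1.10 ± 0.0483 FPKM. Bhlhe40 stood at 17.2 ± 7.69 FPKM against 0.820 ± 0.0542 FPKM. Repair and matrix genes were higher in ST2lo as a list (camera, Benjamini-Hochberg-adjusted p = 9.2e-16, and 0.426 as adjusted p with an estimated correlation). A median of 2.16 was found for the list, and 11 of its 16 members were higher and 0 lower over all genes, 12 and 0 adjusted over the list alone. S100a11 stood at 155 ± 46.5 FPKM against 13.6 ± 2.99 FPKM. Cell cycle genes were higher in ST2lo as a list (camera, Benjamini-Hochberg-adjusted p = 3.33e-06, and 0.464 as adjusted p with an estimated correlation). Of 21 tested members, 3 were higher and 0 lower over all genes, and 11 and 0 adjusted over the list alone (median 0.76). Mki67 stood at 18.9 ± 14.5 FPKM against 0.975 ± 0.0670 FPKM. Ccnb2, a cyclin gene, stood at 3.61 ± 1.37 FPKM against 0.287 ± 0.181 FPKM. Glycolysis genes were higher in ST2lo as a list (camera, Benjamini-Hochberg-adjusted p = 0.00481, and 0.514 as adjusted p with an estimated correlation). Over all genes, 0 of 16 members were higher and 0 lower (1 and 0 after upper-quartile scaling), against 1 and 0 adjusted over the list alone (median 0.41). Slc2a3 stood at 6.27 ± 1.31 FPKM against 1.90 ± 0.495 FPKM. Immediate early genes were higher in ST2lo than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 0.0408, and 0.768 as adjusted p with an estimated correlation). The list had a median of 0.32, with 2 of 22 members higher and 0 lower over all genes and 2 and 0 adjusted over the list alone. Fosb stood at 14.8 ± 4.66 FPKM against 3.04 ± 0.309 FPKM.

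Genes of naive and central memory T cells were lower in ST2lo than in naive cells as a list (camera, Benjamini-Hochberg-adjusted p = 1.47e-12, and 0.426 as adjusted p with an estimated correlation). A median of -0.90 was found for the list, and 0 of its 20 members were higher and 4 lower over all genes (0 and 11 after upper-quartile scaling), 1 and 8 adjusted over the list alone. Igfbp4, Dapl1, Treml2 and Bach2 are among them. Interferon response genes were not called as a list (camera, Benjamini-Hochberg-adjusted p = 0.336). Of 18 tested members, 2 were higher and 0 lower over all genes (1 and 0 after upper-quartile scaling), and 2 and 0 adjusted over the list alone (median -0.27). Ifi27l2a stood at 208 ± 58.4 FPKM against 49.8 ± 8.34 FPKM. Oas3 stood at 3.75 ± 0.377 FPKM against 0.684 ± 0.304 FPKM. Lipid genes were not called, with a test direction opposite to the median, which was 0.0287 after upper-quartile scaling (camera, Benjamini-Hochberg-adjusted p = 0.545). Over all genes, 1 of 16 members were higher and 0 lower (0 and 0 after upper-quartile scaling), against 1 and 0 adjusted over the list alone (median -0.03). Fabp5 stood at 5.73 ± 0.311 FPKM against 1.51 ± 0.0649 FPKM. Ifi27l2a, Oas3 and Fabp5 passed as deposited (limma, Benjamini-Hochberg-adjusted p = 0.0494, 0.0337 and 0.0439). After upper-quartile scaling Oas3 and Fabp5 did not pass. Heat shock genes were not called (camera, Benjamini-Hochberg-adjusted p = 0.946; median 0.15).

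**Figure D3:**
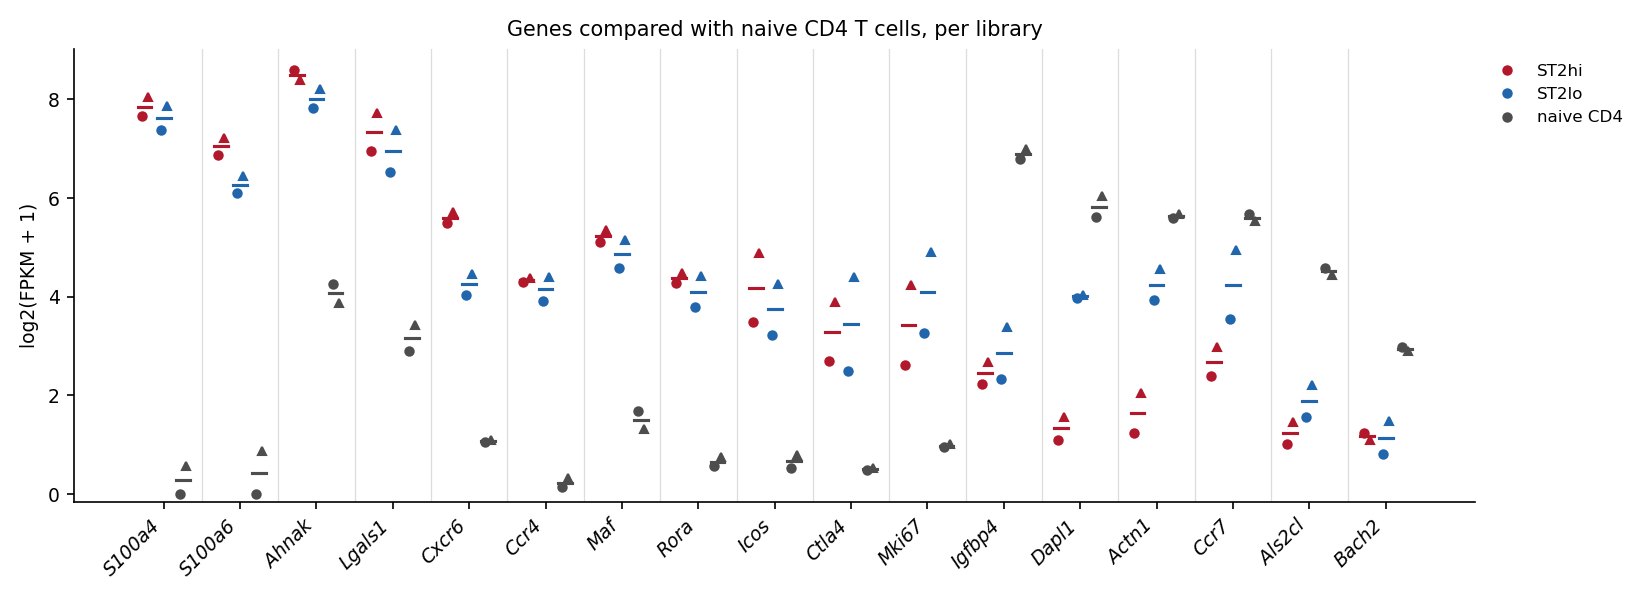
Expression, as log2(FPKM + 1), of genes named in the comparisons with naive cells, in each library of the 3 populations, with circles for replicate 1, triangles for replicate 2 and bars for the mean of both. S100a4 lies at 202 and 262 FPKM in ST2hi and 166 and 231 FPKM in ST2lo, and Igfbp4 at 109.7 and 126 FPKM in the naive libraries.

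The lists of calls against naive cells overlapped. Higher in both ST2hi and ST2lo were 193 genes, lower in both were 22, and none was called in opposite directions. Independent lists of these sizes would share 12.7 higher and 0.195 lower genes. Simulated data with no gene changed, in which both comparisons shared the simulated naive libraries, gave 0.45 higher and 0.52 lower shared genes on average over 100 draws. Data without change give few calls to share (4.37 and 4.47 on average in the draws described for the test). These shared counts therefore do not show how much of the overlap comes from the naive libraries. The covariance of the log2 differences across genes was 0.423, against 0.101 in the simulation, and their correlation 0.743, against 0.504, so part of the agreement is expected from the shared naive libraries. With a separate naive library for each population, an alternative chosen after seeing the data, the covariance was 0.301 and 0.322 and the correlation 0.438 and 0.479 for the 2 ways of dividing them. Each difference then rests on 1 naive library.

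**Figure D4:**
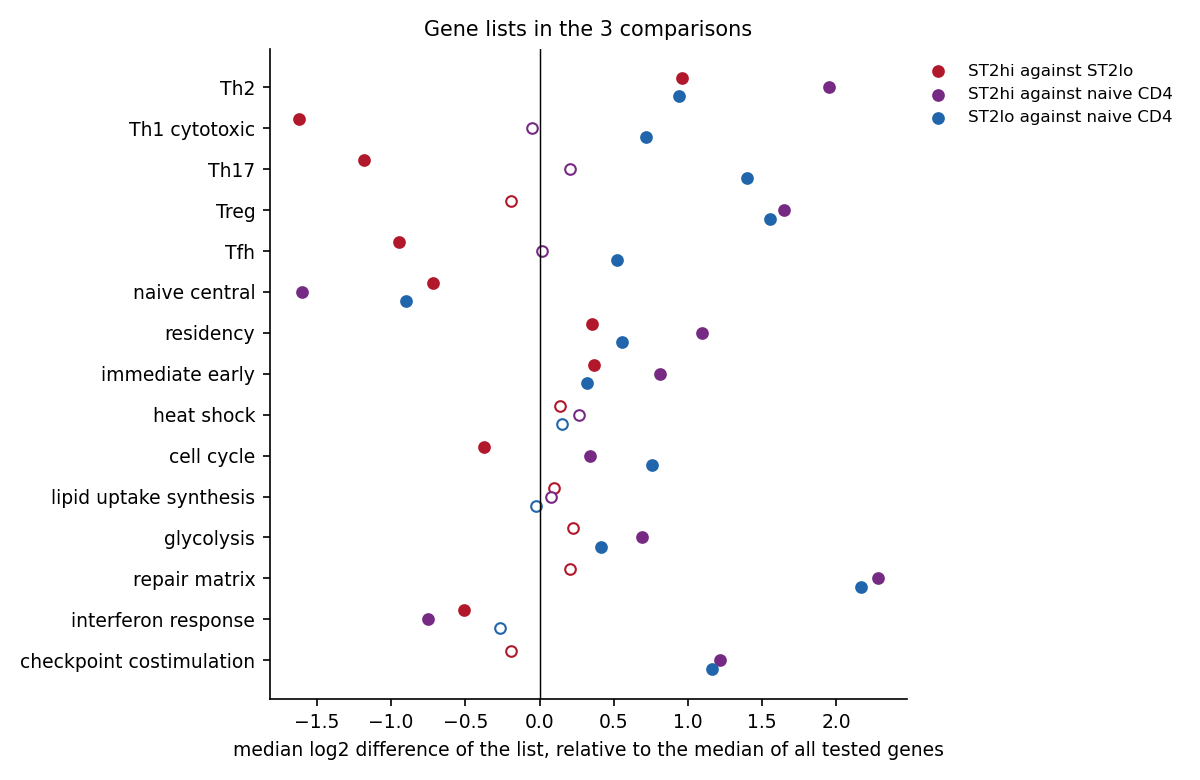
Median log2 difference of the tested members of each of the 15 gene lists, relative to the median of all tested genes, in the 3 comparisons, with filled points for lists that passed camera's test with Benjamini-Hochberg adjustment at the preset correlation and open points for the rest. The type 2 list has medians of 0.96, 1.95 and 0.94, and the type 1 and cytotoxic list -1.62, -0.05 (0.0349 after upper-quartile scaling) and 0.71.

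Marker genes of other cells were summed as FPKM per library, with replicate 1 first. Genes of T cell identity, such as the CD3 chains, summed to 1194 and 1558 in ST2hi, 1042 and 1623 in ST2lo and 763 and 804 in naive cells. B cell and antigen presentation markers summed to 7.12 and 7.34 in ST2hi, 22.1 and 21.1 in ST2lo and 2.82 and 6.003 in naive cells. Cd74 made up most of the ST2lo sums, with 16.1 and 11.9 FPKM. Macrophage and dendritic cell markers summed to 15.3 and 20.2 in ST2hi, 29.0 and 36.1 in ST2lo and 23.2 and 28.9 in naive cells. Granulocyte, mast cell and basophil markers summed to 4.14 and 6.29 in ST2hi, 8.003 and 1.63 in ST2lo and 3.96 and 4.13 in naive cells. CD8 T cell and natural killer cell markers summed to 1.71 and 3.01 in ST2hi, 2.11 and 4.93 in ST2lo and 3.42 and 4.08 in naive cells. Unconventional T cell markers summed to 0.160 and 0.171 in ST2hi, 0.458 and 3.91 in ST2lo and 0.154 and 1.21 in naive cells. Innate lymphoid cell markers summed to 18.8 and 20.5 in ST2hi, 11.1 and 18.5 in ST2lo and 10.1 and 15.4 in naive cells. Ramp1, a receptor activity-modifying protein gene, made up most of the ST2lo and naive sums, at 11.1 and 10.1 FPKM in ST2hi, 9.62 and 14.4 in ST2lo and 9.41 and 12.1 in naive cells. Lung epithelial markers summed to 12.5 and 24.6 in ST2hi, 15.8 and 14.6 in ST2lo and 19.2 and 47.3 in naive cells. Endothelial and stromal markers summed to 13.2 and 15.8 in ST2hi, 10.3 and 20.4 in ST2lo and 21.5 and 44.0 in naive cells. The highest epithelial and endothelial sums were in naive replicate 2. There the endothelial cadherin gene Cdh5, chosen after its values were seen, stood at 7.05 FPKM, against 0.917 FPKM in naive replicate 1. After upper-quartile scaling the order of the means turned for 4 of these lists. T cell identity sums averaged 1186 ± 10.8 in ST2hi, 1232 ± 45.5 in ST2lo and 1047 ± 64.1 in naive cells, against 1376 ± 257, 1333 ± 411 and 784 ± 29.5 as deposited. Macrophage and dendritic sums averaged 31.0 ± 5.99 in ST2lo and 34.6 ± 1.996 in naive cells, against 32.6 ± 5.04 and 26.1 ± 4.06. Granulocyte, mast cell and basophil sums averaged 4.45 ± 0.437, 5.46 ± 6.02 and 5.41 ± 0.370 in ST2hi, ST2lo and naive cells, against 5.22 ± 1.52, 4.82 ± 4.51 and 4.05 ± 0.123. Innate lymphoid sums averaged 13.6 ± 0.0880 in ST2lo and 16.9 ± 3.30 in naive cells, against 14.8 ± 5.17 and 12.8 ± 3.73.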

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

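The settings without short RNA genes, with repeated symbols summed, with upper-quartile scaling combined with another choice, and with separate naive libraries were chosen only after the data were seen. Count models (DESeq2 and edgeR), foreseen in case the files held counts, were not run, because they hold none. A setting without 1 library leaves its group with 1 library, which is then assumed to vary like the other groups. The cause of the changes listed was not tested. The counts of genes (9 for ST2hi against ST2lo, 560 for ST2hi against naive cells and 290 for ST2lo against naive cells) stayed within 1.5 times of these values with a filter at 5 FPKM, without a mean-variance trend and with repeated symbols summed. The count does not show which genes passed: that filter ended the calls of Pparg, Siglech, Klk1 and Irf8 between ST2hi and ST2lo, and a pseudocount of 0.1 ended these and that of Il1rl1.

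For ST2hi against ST2lo the count of genes became 4 (3 higher, 1 lower) with a pseudocount of 0.1, 2 (2 higher, 0 lower) without a filter, 28 (11 higher, 17 lower) with only the groups compared, 46 (20 higher, 26 lower) without short RNA genes, and 20 (5 higher, 15 lower) without them after upper-quartile scaling. For ST2hi against naive cells it became 100 (88 higher, 12 lower) without a filter, 879 (471 higher, 408 lower) after upper-quartile scaling, 883 (496 higher, 387 lower) after quantile normalization, 1520 (1363 higher, 157 lower) with only the groups compared, 953 (849 higher, 104 lower) without short RNA genes and 1136 (583 higher, 553 lower) without them after upper-quartile scaling. For ST2lo against naive cells it became 36 (27 higher, 9 lower) without a filter, 498 (456 higher, 42 lower) without short RNA genes and 610 (374 higher, 236 lower) without them after upper-quartile scaling. Without 1 library, the counts ranged from 11 to 62 (lowest without ST2lo replicate 1, highest without ST2lo replicate 2), 197 to 1507 (without naive replicate 1 and ST2lo replicate 2) and 114 to 639 (without naive replicate 1 and ST2lo replicate 1). The filter and the left-out short RNA genes change which genes are tested.

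The titles give the populations the same replicate numbers, and no label says what a number marks. With the number as a replicate block, the counts were 27 (14 higher, 13 lower), 1779 (1618 higher, 161 lower) and 832 (765 higher, 67 lower) in that order, and after upper-quartile scaling 5 (3 higher, 2 lower), 986 (538 higher, 448 lower) and 420 (283 higher, 137 lower). Between ST2hi and ST2lo, Il1rl1, Pparg, Siglech, Klk1, Dapl1 and Irf8 all passed with the block alone. None of them passed with the block and that scaling together (limma, Benjamini-Hochberg-adjusted p from 0.0709 for Pparg and Dapl1 to 0.1395 for Il1rl1). Across genes, which are not independent replicates, the correlation of the replicate 2 minus replicate 1 difference between both populations was 0.1248, 0.1592 and 0.1268, and after upper-quartile scaling 0.0994, 0.1566 and 0.1293. With 2 numbers only, the libraries were not treated as pairs.

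The number of lists past camera's threshold (9, 10 and 12 of 15) fell to 0 in each comparison with an estimated correlation, and without 1 library ranged from 7 to 9, 9 to 11 and 11 to 12. The medians that changed sign were of lists that had not passed, apart from the follicular list of ST2lo against naive cells. With a filter at 5 FPKM its median was -0.0931 and it no longer passed. In ST2hi against naive cells the type 1 list, -0.05 as reported, was 0.0172 with a pseudocount of 0.1, 0.2505 without a filter, 0.0349 after upper-quartile scaling (with or without the replicate block), 0.0637 after quantile normalization and 0.0339 after upper-quartile scaling without short RNA genes. In ST2lo against naive cells the lipid list, -0.03 as reported, was 0.035, 0.2245, 0.0287, 0.0332 and 0.0277 in the same settings, and 0.0557 with a filter at 5 FPKM. That filter also gave 0.1088 for the regulatory list and 0.0228 for the checkpoint list in ST2hi against ST2lo, and -0.1007 for the follicular list in ST2hi against naive cells. Quantile normalization gave -0.0096 for the follicular list in ST2hi against naive cells and -0.0194 for the heat shock list in ST2hi against ST2lo.

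Without 1 library, medians that changed sign ranged in ST2hi against ST2lo from -0.3445 to 0.2412 (regulatory), -0.2756 to 0.17 (checkpoint) and -0.2033 to 0.4278 (heat shock). In ST2hi against naive cells they ranged from -0.222 to 0.1113 (type 1), -0.0732 to 0.4728 (type 17) and -0.1232 to 0.1199 (follicular), and in ST2lo against naive cells from -0.0385 to 0.1475 (lipid) and -0.286 to 0.4855 (heat shock). The log2 difference of Cd4, not past the threshold, was -0.0062 in ST2hi against naive cells after upper-quartile scaling (with or without the replicate block) and -0.018 without short RNA genes as well, and in ST2hi against ST2lo it ranged from -0.7693 to 0.3728 without 1 library, where that of Ramp1 ranged from -0.4106 to 0.1221. After upper-quartile scaling, 9 of 27 mean marker sums moved by 1 SD or more, 5 to a higher and 4 to a lower value. With separate naive libraries the covariance of both comparisons with naive cells was 0.3012 and 0.3219. The 6 named genes called between ST2hi and ST2lo kept their direction in all 18 alternative settings, and passed in 14 (Pparg, adjusted p from 0.000160 to 0.282), 12 (Il1rl1, 0.000166 to 0.325), 14 (Siglech, 4.25e-05 to 0.282), 12 (Klk1, 4.25e-05 to 0.282), 15 (Dapl1, 0.000724 to 0.283) and 14 (Irf8, 0.000724 to 0.794), by limma with Benjamini-Hochberg adjustment. Without a filter on low values, 22 of 50 named calls of ST2hi against naive cells and 34 of 47 of ST2lo against naive cells were lost. Depth is unknown, so what it limits was not assessed.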

Other observations

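The test of structural cell RNA as the whole cause of the fewer zeros in naive replicate 2 was chosen only after its result was seen. Foxp3, the transcription factor gene of regulatory T cells and chosen here after its values were seen, was present in both CD25-negative populations, at 10.3 ± 3.36 FPKM in ST2hi and 10.7 ± 8.70 FPKM in ST2lo, against 1.24 ± 0.0674 FPKM in naive cells. It was higher than in naive cells in both libraries of each population, and passed for ST2hi (relative log2 difference 1.88; limma, Benjamini-Hochberg-adjusted p = 0.0252) but not for ST2lo (1.81; 0.0516). Ccr3, a chemokine receptor gene known from eosinophils and type 2 helper T cells, stood at 2.48 and 2.63 FPKM in ST2hi, 0.523 and 0.476 in ST2lo and 0.542 and 0.324 in naive cells. Its difference between ST2hi and ST2lo did not pass over all genes. It passed adjusted over the list alone, which had only 3 tested members (limma, Benjamini-Hochberg-adjusted p = 0.00475). No hypothesis was tested for either gene.

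Siglech and Irf8, genes known from plasmacytoid dendritic cells, were higher in ST2lo than in ST2hi, and the gate as labelled names neither a T cell receptor nor a lineage marker. Siglech still differed by 2.98 (log2) after upper-quartile scaling (limma, Benjamini-Hochberg-adjusted p = 0.0412, in a range of 4.25e-05 to 0.282 over 18 settings). This cannot decide on a difference in scale, because the scaling could not have removed a difference of that size. Upper quartiles of the ST2hi and ST2lo libraries lay between 8.27 FPKM (ST2lo replicate 1) and 13.6 FPKM (ST2lo replicate 2). Siglech, chosen as a call from the same data, stood at 0 and 0.384 FPKM in ST2hi and 8.39 and 8.35 FPKM in ST2lo. Plasmacytoid dendritic cells in the ST2lo sort stay open as a candidate source. Of 25 other genes known from them, 6 were left out because a naive library had at least 1 FPKM. The other 19 had a median log2 difference of 0.54 relative to all genes above 0 in any library (camera p = 3.2e-10, and p = 0.0803 with an estimated correlation). That background is wider than the 10073 genes used elsewhere and includes genes below the filter. These p-values are therefore not comparable with those of the other lists. Of these 19, 12 were higher in both ST2lo libraries than in both ST2hi libraries and 1 was lower (chance gives 16.7% each way), with the most abundant, Grn, at 8.22 and 7.54 FPKM in ST2lo against 4.62 and 5.09 in ST2hi. Of the 10073 genes past the filter, a narrower set than that background, 792 were higher in both ST2lo libraries and 1369 lower. Some of the 12 lay below 1 FPKM in every library, such as Spib, Tlr9, Blnk and Paqr5. Expression of plasmacytoid dendritic cell genes by the T cells themselves, the biological alternative between these populations, was not tested.

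Naive replicate 2 listed 2097 genes at 0, fewer than the 7143 to 7904 of the other libraries, and held the highest endothelial and epithelial marker sums. The lowest positive values of olfactory receptor genes (their 10th percentile) were taken as a stand-in for depth. They were 1.15 times the median of the other 5 libraries, where deeper sequencing needs a lower value. Among those 5 this percentile was lowest in ST2hi replicate 2 (0.0548 FPKM, 22.3% of these genes above 0). It was highest in ST2lo replicate 1 (0.169 FPKM, 35.4% above 0), so it did not follow the share above 0. Depth itself is unknown, so this test cannot decide, and deeper sequencing stays open. Olfactory receptor genes are silent in lung, yet 81.4% of 1092 were above 0 here, against 15.02% to 41.4% in the others. That is 40.0 percentage points above the highest, where the others span 26.4. This comparison with the span was set after the shares were seen. It therefore cannot decide on RNA of lung structural cells as the whole cause. Fragments of genomic DNA or unspliced RNA stay open, as does structural cell RNA as a part or the whole of the cause. The ratio to the highest share was 1.97, short of the bound of 2 set beforehand to decide either. No biological explanation was tested.

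The short RNA genes Mir5130, Snord71 and Snord4a were called higher in ST2hi with all-or-none values. Among 47 short RNA genes listed at 0 in exactly 2 or exactly 4 libraries and at 100 FPKM or more in another, the zeros followed the populations in 9, or 19.1% (exact Clopper-Pearson 95% interval 9.15% to 33.3%), where chance gives 20%. These calls may therefore come from erratic FPKM of genes shorter than a sequenced fragment. The calls against naive cells hold such genes too (9 of 70 lower for ST2hi and 12 of 28 for ST2lo). A difference between the populations was not excluded for any of them, and no biological explanation was tested.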
